A study of Mus musculus with 108 samples.

How the data were processed

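RNA was measured in livers of male mice by sequencing. Per the labels' protocols, total RNA was extracted with Trizol and a column kit and made into TruSeq libraries. The 108 labelled libraries fall into 6 sets of 18, at 6 zeitgeber times with 3 replicates each: C57BL/6J (B6) and 129S1/SvImJ (129) wild type on chow or on the high fat and sucrose diet (HFD), Errg-Cre (129, HFD) and Esrrg LKO (B6 by title, with a mixed strain label). The replicates are numbered in the labels, which do not say that they are separate animals, so p-values measure the spread between these samples.

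The deposited signal values are quantile-normalised read numbers per RefSeq transcript, and the authors used STAR and HOMER with the mouse build mm10, per the submitters' processing notes, which give no versions. Each of the 3 tables has 42361 transcripts with 25125 gene symbols. Within a table all libraries have identical sorted values, checked on the files, with a total of 10837743, 12305608 or 10346206 and 23.5%, 27.0% or 27.5% of the values at 0. Quantile normalisation removes the library totals, so depth is unknown, no interval for counting error can be given, and a change shared by most genes cannot be seen. The most abundant transcripts take few distinct values: Alb has 4 in the wild-type table and 44 libraries hold it at the top value. Isoforms of a gene share reads, and reads of near-identical gene copies can be split or misplaced. The mm10 build is the B6 genome, so levels of 129 can be too low where reads carry variants. Coordinates are 1-based in mm10: of 35317 transcripts matched to a reference annotation, 40.6% had the same start, against 2.28% with the start moved by 1. A further 18 columns with no matching label were not used, and control libraries for the knockout were not used here.

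Values were tested as log2(value + 1). A transcript was kept where its mean over the labelled libraries of its table was at least 10, and of transcripts with the same symbol the one with the highest mean was kept. This left 11287 wild-type genes, 11622 in the table with Errg-Cre and 11946 in that with Esrrg LKO. Linear models were fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The wild-type fit had 24 group means. The diet effect in each strain, the strain effect on each diet (129 minus B6) and the diet by strain interaction were contrasts averaged over the 6 times, so the number of times with the same sign stands beside the largest of them. Rhythms were fitted as a cosine with a period of 24 h and tested by a moderated F test on 2 degrees of freedom within a set, and between sets as the difference of the cosine and sine terms (the change vector). The Errg-Cre and Esrrg LKO sets were fitted within their own tables.

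Gene lists for 29 pathways and cell types were written before the data were examined, as were the groups, the designs and most alternatives. They cover the clock, fatty acid and triglyceride synthesis, cholesterol, fatty acid oxidation, lipid droplets, bile acids, gluconeogenesis, xenobiotic metabolism, mitochondrial and ERR targets, amino acids and urea, the unfolded protein response, heat shock, immediate early genes, interferon, acute phase, male-biased and female-biased genes and the cell cycle. The others hold markers of hepatocytes, Kupffer cells, recruited macrophages, stellate cells, sinusoidal endothelium, cholangiocytes, lymphocytes, neutrophils, blood, pancreatic acinar cells and adipocytes. Each list was tested with limma camera (preset correlation 0.01, two-sided), adjusted over 135 tests of 27 lists and 5 contrasts, and again with an estimated correlation. The lymphocyte and acinar lists had too few measured members. Of the 135 tests 35 passed, and 1 passed with an estimated correlation (xenobiotic metabolism in 129). Counts of list members use the adjustment over all genes, and the count adjusted over the list alone is printed where it differs.

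Genes were named by a rule fixed in advance: the 10 largest rises and 10 largest falls of each contrast among genes past the threshold with the same sign at all 6 times, up to 4 of the most changed members past the threshold in each list, the 10 largest rhythm changes or amplitudes, and always Esrrg and the clock genes. Some genes named by this rule are not reported here. Genes named outside it, such as list members below the filter and markers of single libraries, were chosen after their values were seen. For named genes that do not pass after the GC and length correction, this is said where they lead a statement.

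The procedures were tested on simulated data with 200 changed genes. Of 67 genes changed by 1 log2, 91.0% were recovered for the diet effect in B6, 83.6% for that in 129 and 74.6% for the interaction (11287 genes). For rhythm changes in B6 65.7% were recovered, and for the rhythm interaction 43.3%. Of 100 simulated lists of 20 genes for diet in B6, camera called 2 with no shift and 100 with a shift of 0.25. With an estimated correlation it called 5 and 100, so correlated genes were not tested. Alternatives planned in advance were pseudocounts of 0.1 and 5, no filter and a filter of 100, array weights, robust eBayes, time as a factor, a fit over the groups compared only, the replicate number as a block, and leaving out each replicate number or library. Alternatives chosen after seeing the data were the removal of a GC and length trend from each library (splines with 4 degrees of freedom, GC content known for 99.5% of the tested genes), the removal of 2 within-group axes, the log2 Mir6236 level of each library as a covariate (with that gene left out of the test), leaving out the 3 shallow libraries (over 3% of tested genes under a value of 1), leaving out 1 library, and leaving out 2 Errg-Cre libraries whose Arntl and Dbp values stood over 3 log2 apart from both group mates in opposite directions. Ratios of counts were given with their range over leaving out each library once more. Other software was the R package data.table (1.17.8), Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.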

Results

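Liver RNA of male mice was sequenced in 108 libraries, to ask how genetic background and a high fat and sucrose diet (HFD) shape daily gene expression in the liver. The mice were C57BL/6J (B6), an inbred strain prone to diet-induced obesity, and 129S1/SvImJ (129), a second inbred strain. Livers were taken at zeitgeber times (ZT, hours after lights on) 2, 6, 10, 14, 18 and 22, with 3 replicates per time. Wild-type mice of each strain were fed chow or HFD, which gives 4 sets of 18 libraries. A further 18 libraries were labelled Errg-Cre (129, HFD) and 18 were labelled Esrrg LKO (B6, diet-induced obesity). The values are quantile-normalised read numbers per transcript, so the sequencing depth of each library is unknown. Every library of a table has the same total (10837743 for wild type, 12305608 with Errg-Cre, 10346206 with Esrrg LKO). The 3 tables were normalised separately, so expression levels were tested only within a table, and between tables only peak times of clock genes were compared. Fold changes are on the log2(value + 1) scale, with their standard error, and level means are given with their SD (n = 18 libraries per set).

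Some libraries stood apart. In B6 chow ZT14 replicate 3, 14.8% of the tested genes had a value under 1. The share was 6.95% in 129 chow ZT22 replicate 3 and 3.25% in B6 HFD ZT6 replicate 1. The dependence of a library's values on the GC content of the transcripts also differed between sets. It was measured after each gene's mean over its table was subtracted, so a slope of 0 is the average of the table and not an absence of GC dependence. On this relative scale it averaged −0.42 ± 0.46 log2 per 10 GC points in B6 chow and 0.19 ± 0.12 in B6 HFD, a difference of 0.61 (permutation test, p = 1e-05, the smallest possible, adjusted p = 8e-05 over 8 tests). Slopes averaged 0.10 ± 0.55 in 129 chow and 0.14 ± 0.15 in 129 HFD, a difference of 0.043 (permutation p = 0.75, adjusted p = 0.798). In 129 chow the mean slope was −0.53 at ZT2, −0.40 at ZT6, 0.61 at ZT18 and 0.54 at ZT22, and the differences between times did not pass after adjustment (permutation p = 0.019, adjusted p = 0.0507). The Errg-Cre libraries gave a permutation p of 0.019 across times as well (adjusted p = 0.0507).

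The non-coding RNA gene Mir6236 also set libraries apart. In 129 chow it was at 27.7 to 3213 in 10 libraries, those of ZT2 to ZT10 and ZT14 replicate 1, and at 35151 to 61431 in the other 8, so this split goes with time. In B6 it went with diet, at 32.8 to 1171 on chow and 915 to 91012 on HFD, while it was at 294 to 4030 in 129 HFD. Tests were therefore repeated with the Mir6236 level of each library as a covariate, an alternative chosen after seeing the data.

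**Figure D1:**
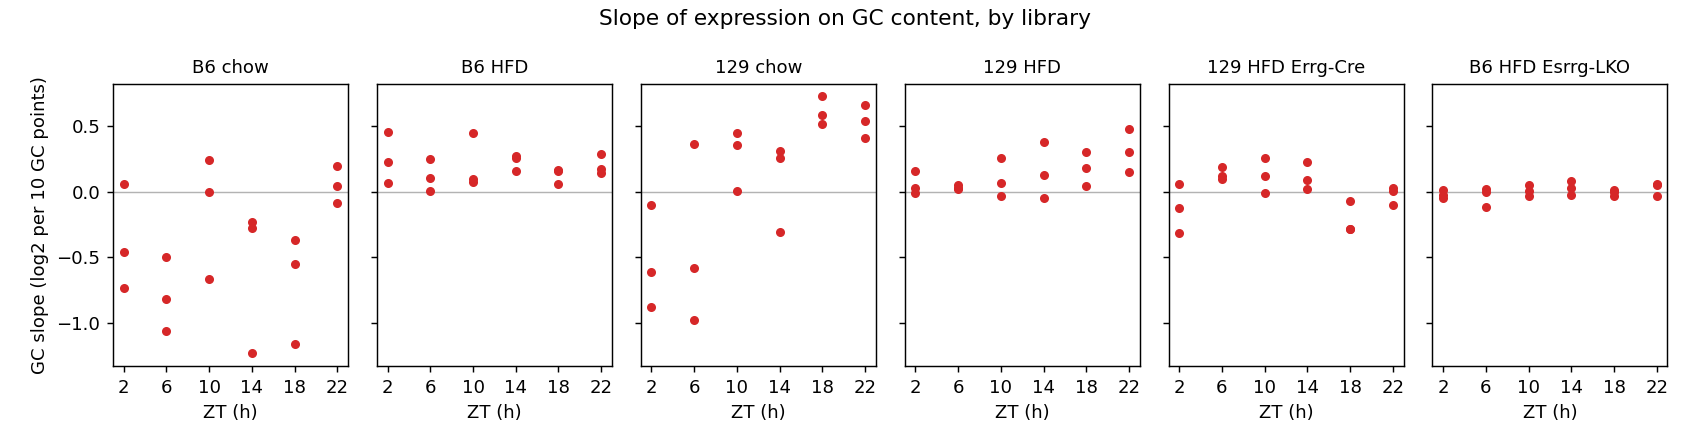
GC slope of each library relative to the mean of its table (vertical axis, log2 value per 10 GC points) against zeitgeber time (horizontal axis, h) in the 6 sets. Each point is a library and the grey line marks 0, the mean of a table, so levels compare only among the 4 wild-type sets. The 129 chow means are −0.53 at ZT2 and 0.54 at ZT22.

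Esrrg encodes the orphan nuclear receptor ERR gamma and lies on chromosome 1 (187609006 to 188214884, mm10). Its level was 18 ± 12.9 in B6 chow, 29.0 ± 12.8 in B6 HFD, 19.7 ± 10.33 in 129 chow and 30.3 ± 13.4 in 129 HFD. Esrrg rose with HFD in B6 (log2 0.92 ± 0.26, limma adjusted p = 0.00213, higher at 5 of 6 times) and in 129 (log2 0.78 ± 0.26, adjusted p = 0.0276, higher at 4 of 6 times). Values of 0 in B6 chow ZT14 replicate 3 and 129 chow ZT18 replicate 1 add to these rises. With the Mir6236 covariate the B6 rise was as large, with a wider error, but did not pass (1.01 ± 0.47, adjusted p = 0.233). The diet effects did not differ between strains by the test of the difference (log2 −0.14, adjusted p = 0.787). Nor did the strains differ on chow (log2 0.25, adjusted p = 0.424) or on HFD (log2 0.11, adjusted p = 0.79). The Errg-Cre libraries had a level of 27.4 ± 13.6 and the libraries labelled Esrrg LKO 17.7 ± 8.36. These come from separately normalised tables, and their own control libraries were not used here, so the knockout was not tested. A total per transcript can also miss a deleted exon, because reads from the rest of the transcript still count. Esrrg did not pass the rhythm test in any of the 6 sets.

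In B6 livers HFD raised the apolipoprotein gene Apoa4 and lowered the drug-metabolising cytochrome P450 gene Cyp3a11. Apoa4 (chromosome 9, 46240844 to 46243458) went from 135 ± 85.0 to 5056 ± 5386 (log2 4.80 ± 0.31, limma adjusted p = 2.58e-18), and Cyp3a11 (chromosome 5, 145854607 to 145879854) from 224650 ± 152260 to 7182 ± 2879 (log2 −4.97 ± 0.37, adjusted p = 6.55e-16). Cfd, which encodes the complement protease adipsin, rose from 2.17 ± 2.32 to 89.5 ± 65.0 (log2 4.66 ± 0.37, adjusted p = 4.83e-15). The helix-loop-helix factor gene Tcf24 fell from 120 ± 50.2 to 2.24 ± 2.75 (log2 −5.49 ± 0.23, adjusted p = 2.68e-26), and Asns, the asparagine synthetase gene, from 86.1 ± 41.2 to 12.2 ± 27.1 (log2 −3.65 ± 0.35, adjusted p = 1.46e-12). All 5 moved the same way at all 6 times.

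The other large rises in B6 were those of the non-coding RNA genes Mir6236 (log2 5.50 ± 0.51), Mir6240 (4.50), Rpph1 (3.34) and Snora78 (3.04), and of Themis (4.06), Gpc1 (3.88), Rpl36 (3.39) and Mfsd2a, a lysophospholipid transporter gene (3.10). The other large falls were Cyp2c55 (−5.10 ± 0.22), Cyp2b10 (−5.08), Cyp2c40 (−5.31), Cyp2c69 (−4.30), Cyp4a12b (−3.47), Cyp2c53-ps (−3.36) and Gstm3 (−3.31). These cytochrome P450 and glutathione transferase genes belong to families with near-identical copies, so the split of reads between copies is uncertain.

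Lipid genes rose together in B6. Of the 14 measured lipid droplet and PPAR gamma target genes, 11 rose and 0 fell, among them Cidec (log2 2.77), G0s2 (2.64), Plin4 (2.35) and the droplet coat gene Plin2 (1.83). The camera test gave adjusted p = 0.000118, and 0.366 with an estimated correlation. Of 24 fatty acid oxidation and PPAR alpha target genes, 13 rose and 4 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.00144, and 0.722 with an estimated correlation). Fgf21, a fasting hormone gene, rose by 2.96, Acaa1b by 1.22, Cpt1a by 1.12 ± 0.08 and the lipase inhibitor gene Angptl4 by 1.10. Cpt1a, the carnitine palmitoyltransferase that brings fatty acids into mitochondria, went from 1596 ± 439 to 3410 ± 622. Of 18 fatty acid and triglyceride synthesis genes, 10 rose and 2 fell (adjusted p = 0.0044, and 0.798 with an estimated correlation). Fads2 (1.61), the lipogenic factor gene Srebf1 (1.56) and Fasn (1.54) rose and Scd1, the stearoyl-CoA desaturase gene, fell (−1.61). Of 22 cholesterol synthesis and uptake genes, 11 rose and 1 fell, with Mvd (2.45), Mvk (2.01), Pmvk (1.58) and Fdps (1.18) leading (adjusted p = 0.0098, and 0.866 with an estimated correlation). With the GC and length trend of each library removed, the fatty acid synthesis list no longer passed (median 0.503 before and 0.211 after, adjusted p = 0.0615). Of the lipid genes named here, only Fads2, Mvk, Fgf21, Cpt1a and Plin2 passed with the Mir6236 covariate, where Srebf1 was at 0.35 and Fasn at 0.47.

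Genes of xenobiotic metabolism fell in B6, 16 of 22 against 2 that rose (17 and 3 adjusted over the list alone; camera adjusted p = 4.13e-05, and 0.319 with an estimated correlation). Male-biased liver genes fell as well, 9 of 13 with 2 rising (10 and 2 adjusted over the list alone; adjusted p = 0.00678, and 0.722 with an estimated correlation). Among them were Cyp4a12a (−2.59), Serpina1e (−2.33) and the steroid dehydrogenase gene Hsd3b5 (−2.11). Of 5 female-biased genes, Cyp2b9 (4.79, 5 of 6 times) and Cyp17a1 (1.81) rose and Cyp2a4 fell (−2.25), and the list did not pass (adjusted p = 0.469). Heat shock genes fell, 9 of 12 with 2 rising, led by Hspa1b (−1.40), Hspe1 (−0.62) and Hsph1 (−0.58) (adjusted p = 0.0439, and 0.798 with an estimated correlation). That call ended without the 3 shallow libraries (adjusted p = 0.0768).

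Markers of other cell types moved with the diet in B6. Of 10 stellate cell and fibrosis markers, 7 rose and 0 fell, including the collagen genes Col1a1 (1.43, lost after the GC and length correction, adjusted p = 0.109), Col3a1 (1.29) and Col4a1 (1.13) and the receptor gene Pdgfrb (1.15) (camera adjusted p = 0.0049, and 0.319 with an estimated correlation). Of 13 Kupffer cell (resident macrophage) markers, 8 rose and 0 fell, among them the complement genes C1qb (1.55) and C1qa (1.41), Cd5l (0.92) and Csf1r (0.90) (adjusted p = 0.00956, 0.722 with an estimated correlation, and 0.0836 after the GC and length correction, with a median of 0.744 before and 0.354 after). Sinusoidal endothelial markers split into 7 rising, led by Stab1 (1.5), and 2 falling of 13 (adjusted p = 0.133). Hepatocyte markers split into 8 rising and 3 falling of 14 (adjusted p = 0.15), with Ttr at 1.30, Ambp at 1.07 and Apoc3 at 1.04. Alb, the albumin gene, fell by 1.73, but 44 of the 72 libraries hold it at the top value of the table, 863453, so its change is limited by saturation. Recruited macrophage and monocyte markers had 2 rising and 2 falling of 7 (adjusted p = 0.795), with Cd9 at −1.22 and Fabp5 at −0.96. Cholangiocyte markers had 2 rising of 4, Spp1 (1.23) and Krt23 (0.87) (adjusted p = 0.567). Of 5 erythroid genes the alpha globin copies Hba-a2 (1.33) and Hba-a1 (1.21) rose, neither after the GC and length correction (adjusted p for the list 0.462). Of the 3 measured adipocyte markers Cfd and Lipe (1.35) rose (adjusted p = 0.124), while Adipoq stayed at means of 0.355 and 0.446. Ptprc, the only lymphocyte marker tested, was at 124 and 161, and Cela1, the only pancreatic acinar gene tested, rose by 0.94.

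Acute phase genes of the B6 livers rested in part on B6 HFD ZT22 replicate 3, which held Saa1 at 110330 and Lcn2 at 10880, above the other 107 libraries. Of 17 genes 8 rose and 4 fell (camera adjusted p = 0.292), and 6 rose and 4 fell without that library. Lcn2 (2.56), Saa2 (2.18) and the haptoglobin gene Hp (1.84) rose and the metallothionein gene Mt2 fell (−1.32). Saa1 (1.29) was at 0.96 without the library (adjusted p = 0.0802). By the limma test 0 of 4 tested neutrophil markers changed with diet (adjusted p = 0.512). Of 8 cell cycle genes Mcm2 (1.20) and Mcm5 (1.05) rose and Ccne2 fell (adjusted p = 0.704). Without that library the adipocyte list passed (adjusted p = 0.0316) and recruited macrophage markers had 0 rising and 3 falling.

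The remaining lists of B6 did not pass. Bile acid genes split 8 rising to 7 falling of 17 (8 and 8 adjusted over the list alone, camera adjusted p = 0.795), with a median of −0.164 and a mean of 0.0319. The repressor gene Nr0b2 rose by 1.98 and the transporter gene Slco1a1 fell (−1.46). Gluconeogenesis genes split 6 to 4 of 16 (adjusted p = 0.363), with Pcx (2.0) rising and Foxo1 falling (−0.76). Mitochondrial and ERR target genes split 9 to 6 of 21 (adjusted p = 0.277), with Cox4i1 at 1.64 and Esrra, which encodes ERR alpha, at 1.62. Amino acid and urea cycle genes split 5 to 7 of 15 (5 and 8 adjusted over the list alone, adjusted p = 0.866), with Gpt at 1.48. Of 14 unfolded protein response genes 3 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.96), with Dnajb9 at −1.41. Of 14 interferon response genes 4 rose and 1 fell (adjusted p = 0.357), with Oasl1 at 1.48. Of 5 immediate early genes Klf6 (0.73) and Btg2 (0.56) rose and Dusp1 fell (−0.58) (adjusted p = 0.781). Of 19 clock genes 5 rose and 4 fell in their mean over the day (5 and 3 adjusted over the list alone, adjusted p = 0.912), with a median of −0.00949 and a mean of 0.0924. Per1 (1.05), Dbp (0.999) and Nr1d1 (0.97) rose and lost their call after the GC and length correction. For the recruited macrophage list the median was 0.16 and the mean −0.0729, and for the unfolded protein response list 0.0282 and −0.0427.

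Over all 11287 genes tested, 6792 changed with diet in B6 (limma, adjusted p below 0.05), 3105 up and 3687 down. Of these, 1081 changed at least 2-fold, 836 up and 245 down, and 3986 had the same sign at all 6 times. With the GC and length trend of each library removed, 5211 genes changed, 2760 up and 2451 down, and 184 calls had turned direction. With the Mir6236 level as a covariate 564 genes changed, 230 up and 334 down. Of 6791 genes called without it, 76.0% kept their sign and 511 their call, while their median effect went from 0.55 to 0.22 log2 and its median standard error from 0.12 to 0.20. Apoa4, Cfd, Tcf24, Cyp3a11 and Asns passed with the covariate and the same sign, as did the 9 lists that passed without it. Some lists were weaker with it. Their medians went from 0.503 to 0.147 for fatty acid synthesis (adjusted p = 0.0498, 3 of 18 genes rising), 0.744 to 0.334 for Kupffer cell markers, 0.886 to 0.47 for stellate cell markers (3 of 10 rising) and −0.461 to −0.257 for heat shock genes (2 of 12 falling). Of 106 named genes called in B6, however, 28 passed, 71 did not and 7 changed sign.

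In 129 livers HFD raised Sult1e1, the estrogen sulfotransferase gene, and again lowered Cyp3a11. Sult1e1 (chromosome 5, 87575968 to 87591611) went from 3.47 ± 4.76 to 109 ± 61.1 (log2 4.88 ± 0.30, limma adjusted p = 7.58e-19), and Cyp3a11 from 133910 ± 125430 to 3540 ± 1445 (log2 −4.95 ± 0.37, adjusted p = 4.24e-15). Fgf21 rose from 3.69 to 30.1 ± 21.0 (log2 3.12 ± 0.40, adjusted p = 4.05e-08). Scd1 (chromosome 19, 44394450 to 44407709) fell from 26028 ± 7464 to 3627 ± 4211 (log2 −3.26 ± 0.41, adjusted p = 2.39e-08). Each moved the same way at all 6 times. The other large rises were Pcdh11x (4.57 ± 0.33), the serum amyloid genes Saa2 (3.31) and Saa1 (2.55), the trehalase gene Treh (2.99), Osbpl3 (2.77), the melatonin receptor gene Mtnr1a (2.69), Adgrv1 (2.64) and Aatk (2.57). The other large falls were Cyp2a4 (−4.49), Cyp2c55 (−4.39 ± 0.22), Cyp2b10 (−3.47), Cyp2c53-ps (−3.19), Acsm2 (−3.04), Gstm3 (−2.54), Hamp2 (−2.52) and Tcf24 (−2.40). Reads of Saa1 and Saa2, and of the cytochrome P450 copies, may be shared between paralogs.

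Fatty acid oxidation genes rose in 129, 12 of 24 with 1 falling (15 and 1 adjusted over the list alone; camera adjusted p = 1.37e-06, and 0.389 with an estimated correlation), with Acadm at 0.65. Cholesterol synthesis genes rose, 10 of 22 with 1 falling, led by Sqle (1.30), Fdps (1.07), Msmo1 (1.0) and Hmgcs1 (0.99) (adjusted p = 0.00122, and 0.798 with an estimated correlation). Lipid droplet genes rose, 5 of 14 with 0 falling (6 and 0 adjusted over the list alone), including the fatty acid transporter gene Cd36 (1.23), Fitm1 (1.21), Plin2 (1.13) and Plin5 (0.57) (adjusted p = 0.00245, and 0.543 with an estimated correlation). Fatty acid and triglyceride synthesis genes had 2 rising and 4 falling of 18 (adjusted p = 0.0595, and 0.0304 without B6 HFD ZT22 replicate 3), with Acacb at −1.27 and Me1 at −1.0, and Pklr at 0.84.

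Xenobiotic metabolism genes fell in 129, 12 of 22 with 2 rising (15 and 3 adjusted over the list alone), and this list alone kept its call with an estimated correlation (camera adjusted p = 2.56e-13, and 0.0405 with an estimated correlation). Interferon response genes rose, 6 of 14 with 0 falling (8 and 0 adjusted over the list alone), with Oasl1 (1.26), Ifit1 (0.87) and Ddx60 (0.69) (adjusted p = 0.00137, and 0.366 with an estimated correlation). Acute phase genes rose, 8 of 17 with 1 falling (9 and 3 adjusted over the list alone), including Saa3 and Lcn2 (2.23 each) (adjusted p = 0.0333, and 0.882 with an estimated correlation). Kupffer cell markers rose, 6 of 13 with 0 falling (7 and 0 adjusted over the list alone), with the scavenger receptor gene Marco (2.12), Cd5l (0.84), Adgre1 (0.81) and C1qa (0.62) (adjusted p = 0.00424, and 0.675 with an estimated correlation).

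Other lists did not pass in 129. Mitochondrial and ERR target genes had 1 rising and 3 falling of 21 (adjusted p = 0.328, and 0.0363 after the GC and length correction), with Ppargc1b, a coactivator gene of ERR proteins, at −0.80. Amino acid genes had 2 rising and 4 falling of 15 (2 and 6 adjusted over the list alone; adjusted p = 0.0985, and 0.0363 after that correction), with Ass1 at −0.62. Gluconeogenesis genes split 4 to 4 of 16 (5 and 4 adjusted over the list alone, adjusted p = 0.866), with Tat at −0.82. Stellate cell markers had 2 rising and 1 falling of 10 (adjusted p = 0.636), with Col1a2 at −0.78. Hepatocyte markers had 3 rising and 1 falling of 14 (6 and 1 adjusted over the list alone, adjusted p = 0.465), with Trf at 1.07. Male-biased genes had 3 rising and 2 falling of 13 (4 and 2 adjusted over the list alone, adjusted p = 0.704), with Cyp4a12b at −1.97. Bile acid genes split 3 to 3 of 17 (adjusted p = 0.954), with Abcb4 at 0.71, and immediate early genes had 2 rising of 5 (3 adjusted over the list alone, adjusted p = 0.271), with Klf6 at 0.91. Unfolded protein response genes had 3 rising and 1 falling of 14 (adjusted p = 0.727), and heat shock genes 0 rising and 2 falling of 12 (adjusted p = 0.909). Recruited macrophage markers had 1 rising, the monocyte receptor gene Ccr2 (1.90), and 1 falling of 7 (2 and 1 adjusted over the list alone, adjusted p = 0.866). Sinusoidal markers split 2 to 2 of 13 (3 and 2 adjusted over the list alone, adjusted p = 0.95), female-biased genes 1 to 1 of 5 (adjusted p = 0.608) and cholangiocyte markers 1 to 0 of 4 (adjusted p = 0.866). Clock genes had 2 rising of 19, Nfil3 (0.60) and Bhlhe40 (0.30) (adjusted p = 0.883), and erythroid genes 1 of 5, Hbb-bt (0.91) (adjusted p = 0.608). By the limma test 0 of 8 cell cycle, 0 of 4 neutrophil and 0 of 3 adipocyte markers changed (adjusted p = 0.896, 0.796 and 0.469 by camera). Median, mean and test did not share a sign for the clock, bile acid, gluconeogenesis, heat shock, female-biased and cell cycle lists.

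In all, 2071 genes changed with diet in 129 (limma, adjusted p below 0.05), 1230 up and 841 down (59.4% up). Of these 161 changed at least 2-fold, 100 up and 61 down, and 1184 had the same sign at all 6 times. With the GC and length trend removed the split moved to 1157 up and 1223 down (48.6% up). When Mir6236 was a covariate 2606 genes changed, and 1909 of the 2071 calls passed with the same sign, as did all 7 lists. Diet raised 731 genes in both strains (338 for independent lists) and lowered 633 in both (275 for independent lists), and 101 moved in opposite directions (633 for independent lists). The diet effects of the strains share no libraries and were correlated across genes (Pearson r 0.464, Spearman rho 0.456), though genes are not independent replicates.

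**Figure D2:**
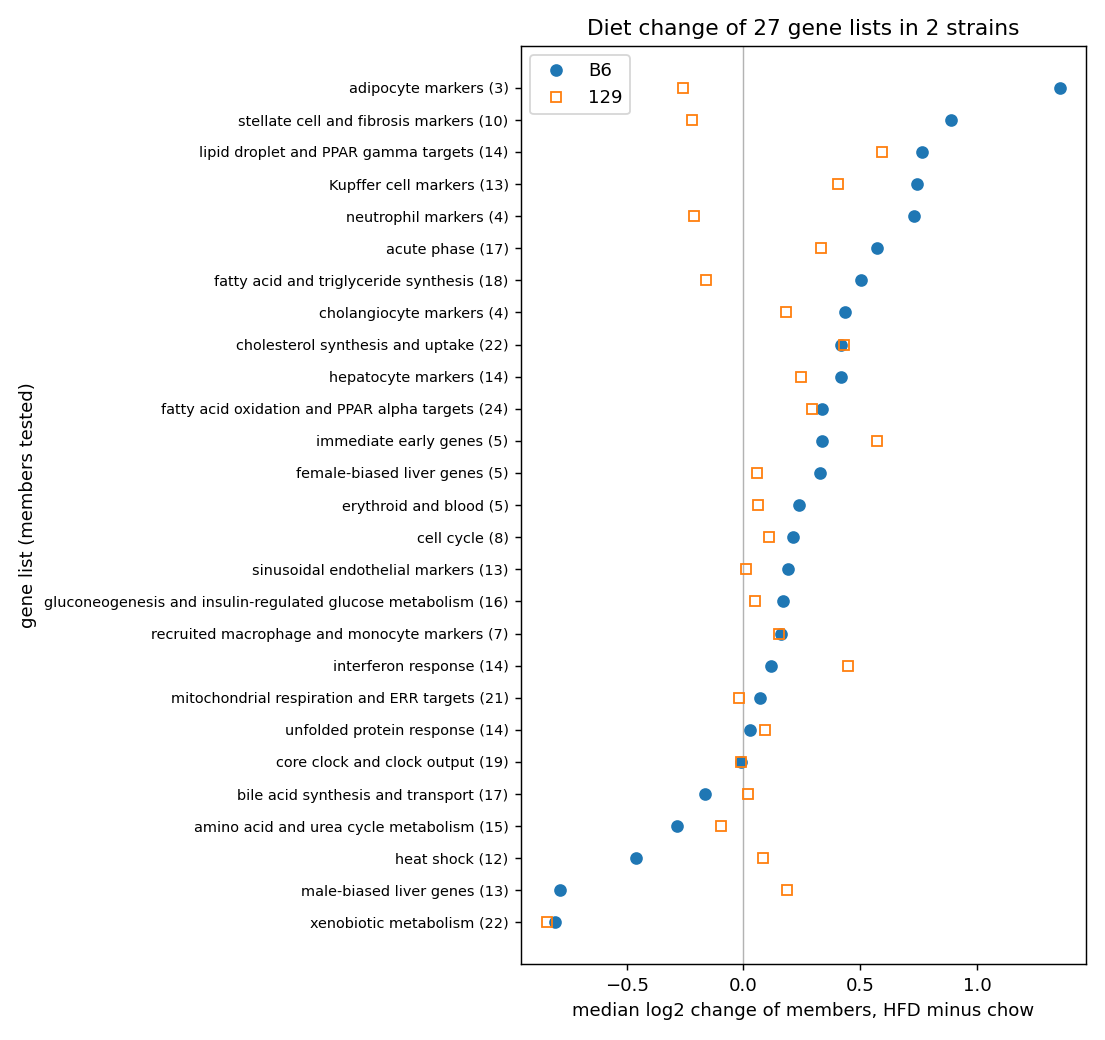
Median log2 diet change (HFD minus chow, horizontal axis) of the tested members of 27 gene lists (vertical axis), with B6 as filled circles and 129 as open squares. Xenobiotic metabolism lies low in both strains (12 of 22 members fell in 129 and 16 in B6), while the stellate cell list lies above 0 in B6 (7 of 10 rose) and not in 129.

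The test of the difference between the diet effects (129 minus B6) asks which responses depend on strain. Sult1e1 rose in 129 and was at 2.81 and 2.48 in B6 (difference 4.76, limma adjusted p = 4.13e-12). Apoa4 rose less in 129, from 2709 ± 1483 to 8014 ± 2421 (difference −2.98, adjusted p = 3.03e-06), and Cfd was at 0.437 and 0.138 in 129 (difference −4.92, adjusted p = 1.75e-09). Asns, which fell in B6, was at 53.5 ± 29.0 and 42.6 ± 17.2 in 129 (difference 3.64, adjusted p = 7.21e-07). All 4 differences had the same sign at all 6 times. Tcf24 fell further in B6 than in 129 (difference 3.09, adjusted p = 1.04e-09). Esrra rose in B6 from 19.3 to 52.2 and was at 65.5 and 35.5 in 129 (difference −2.11 ± 0.29, adjusted p = 7.9e-07).

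Fatty acid and triglyceride synthesis genes responded lower in 129 than in B6 for 13 of 18 members and higher for 0 (14 and 0 adjusted over the list alone), with Srebf1 (−1.88), Fasn (−1.73), Scd1 (−1.65) and Acacb (−1.55) leading (camera adjusted p = 9.45e-07, and 0.427 with an estimated correlation). Stellate cell markers followed, with 6 of 10 lower and 0 higher, the collagen genes Col1a1 (−2.22), Col3a1 (−1.76 ± 0.30), Col1a2 (−1.62) and Col4a1 (−1.40) among them (adjusted p = 0.000195, and 0.196 with an estimated correlation). Male-biased genes responded higher in 129, 10 of 13 and 0 lower, with Serpina1e (2.51), Cyp4a12a (2.32) and Mup20 (1.64) (adjusted p = 0.000451, and 0.543 with an estimated correlation). Heat shock genes were higher for 7 of 12 and lower for 0, with Hspa1b at 1.90 (adjusted p = 0.0197, and 0.722 with an estimated correlation). Lipid droplet genes were lower for 7 of 14 and higher for 0, with G0s2 at −1.96 and Cidec at −1.82 (adjusted p = 0.0161, 0.722 with an estimated correlation, and 0.069 after the GC and length correction, with a median of −0.491 before and −0.446 after). Mitochondrial and ERR target genes were lower for 8 of 21 and higher for 3, with Cox4i1 (−1.44) and Uqcrc1 (−0.82) (adjusted p = 0.0326, and 0.798 with an estimated correlation). Of 3 adipocyte markers Cfd and Lipe (−1.54) were lower (adjusted p = 0.0101, and 0.319 with an estimated correlation).

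The other lists did not pass the test of the difference. Sinusoidal markers had 0 higher and 3 lower of 13 (adjusted p = 0.0831, and 0.0125 after the GC and length correction), with Stab1 at −1.23. Gluconeogenesis genes had 1 higher and 4 lower of 16 (adjusted p = 0.177), with Pcx at −1.37. Cholesterol genes had 5 higher and 7 lower of 22 (6 and 7 adjusted over the list alone, adjusted p = 0.469), with Mvd at −1.84, and fatty acid oxidation genes 1 higher and 5 lower of 24 (1 and 3 adjusted over the list alone, adjusted p = 0.523), with Cpt1a at −0.48. Bile acid genes had 5 higher and 3 lower of 17 (adjusted p = 0.866), with Nr0b2 at −1.96, xenobiotic genes 5 and 2 of 22 (adjusted p = 0.512), with Gsta1 at 1.83, and amino acid genes 4 and 6 of 15 (adjusted p = 0.459), with Gpt at −1.32. Clock genes split 4 to 4 of 19 (5 and 4 adjusted over the list alone, adjusted p = 0.96), with Nfil3 at 0.65. Interferon genes had 2 higher of 14 (1 adjusted over the list alone, adjusted p = 0.61), with Mx2 at 0.89, acute phase genes 2 of 17 (0 adjusted over the list alone, adjusted p = 0.982), with Saa3 at 1.66, and unfolded protein response genes 1 of 14, Dnajb9 at 0.85 (adjusted p = 0.795). Kupffer cell markers split 2 to 2 of 13 (2 and 4 adjusted over the list alone, adjusted p = 0.32), with Marco at 1.38, and hepatocyte markers 2 to 5 of 14 (adjusted p = 0.213), with Apob at 1.38 and Ttr at −0.92. Recruited macrophage markers had 2 higher of 7 (1 adjusted over the list alone, adjusted p = 0.61), with Cd9 at 0.92, erythroid genes 1 higher and 2 lower of 5 (adjusted p = 0.636), cell cycle genes 1 lower of 8, Mcm5 at −1.34 (adjusted p = 0.623), and female-biased genes 2 lower of 5, Cyp2b9 at −4.73 and Cyp2a4 at −2.23 (adjusted p = 0.124). By the limma test 0 of 5 immediate early, 0 of 4 cholangiocyte and 0 of 4 neutrophil genes differed (adjusted p = 0.781, 0.581 and 0.353 by camera). Median and mean had opposite signs for the clock, cholesterol, fatty acid oxidation, bile acid, amino acid and acute phase lists.

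Diet effects differed between the strains for 3881 genes (limma, adjusted p below 0.05), 2272 higher in 129 and 1609 lower (58.5% higher). At least a 2-fold difference was seen for 770 genes, 199 higher and 571 lower. With the GC and length trend removed 1927 genes differed, 782 higher and 1145 lower (40.6% higher), so the number and the split of these calls depend on that trend. With the Mir6236 covariate 14 genes differed, 9 higher and 5 lower. The median effect of the 3880 calls went from 0.58 to 0.18 log2 and its standard error from 0.16 to 0.24. Sult1e1, Tcf24 and Cfd passed with it, while Asns (3.28 ± 0.78, adjusted p = 0.0604), Apoa4 (−1.67 ± 0.66, adjusted p = 0.499) and Esrra (−0.71 ± 0.38, adjusted p = 0.74) did not. Of the 7 lists that passed, lipid droplet genes (median −0.491 before and −0.116 with it, adjusted p = 0.384) and mitochondrial and ERR targets (−0.0475 and 0.0183, adjusted p = 0.181) did not pass with the covariate. The unfolded protein response (adjusted p = 0.00405), female-biased (0.0101) and cell cycle (0.0192) lists passed only with it.

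Between the strains, the largest differences on chow were those of Gm4737 (chromosome 16, 46152991 to 46155077), at 8.86 in B6 and 2159 ± 706 in 129 (log2 8.30 ± 0.26, limma adjusted p = 5.38e-33), of the muscle M-band gene Myom2 (chromosome 8, 15057653 to 15133419), at 0.0439 and 186 ± 87.5 (7.35 ± 0.16, adjusted p = 1.41e-41), and of Urml (chromosome 13, 68228436 to 68234731), at 263 ± 90.3 and 0.129 (−7.83 ± 0.15, adjusted p = 5.71e-43). All 3 differed the same way at all 6 times on either diet. Other genes higher in 129 on chow were the cathepsin gene Ctse (6.66), Serpina3c (6.58), Wdr72 (5.91), Mettl7a3 (5.39), Mup9 (5.27), Cyp2a4 (5.13), Cyp2c39 (5.11) and Cd1d2 (5.07). Lower in 129 were the major urinary protein genes Mup11 (−9.08 ± 0.55) and Mup14 (−7.17), Zfp982 (−7.09), Serpina1e (−6.45), Gm1966 (−5.99), Nlrp12 (−5.96), Ugt2b38 (−5.87), 4930412C18Rik (−5.48) and the neprilysin gene Mme (−5.47). On HFD the odorant-binding protein gene Obp2a (5.85), BC018473 (5.2) and the renin gene Ren1 (5.11) joined the genes higher in 129, and Cyp2b9 (−7.17) and Cfd (−5.83 ± 0.37, adjusted p = 1.99e-19) those lower. Reads were aligned to mm10, which is the B6 genome, so reads of 129 that carry variants or extra gene copies can be lost or misplaced, above all in the Mup, Serpina and Cyp families, in Zfp982 and in Gm4737.

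Genes of cholesterol synthesis were lower in 129 than in B6 on chow, 15 of 22 with 3 higher, led by Hmgcs1 (−2.29 ± 0.17, from 2945 ± 1287 in B6 to 580 ± 232 in 129), Idi1 (−1.90), Cyp51 (−1.81) and Sqle (−1.77) (camera adjusted p = 4.13e-05, and 0.669 with an estimated correlation). Interferon response genes were lower for 12 of 14 and higher for 0, with Oasl1 (−1.97), Ifit1 (−1.59), Ddx60 (−1.51) and Usp18 (−1.38) (adjusted p = 7.97e-05, and 0.319 with an estimated correlation). Heat shock genes were lower for 9 of 12 and higher for 0 (11 and 0 adjusted over the list alone), with Hspa1b at −2.17 and Hspb1 at −1.94 (adjusted p = 0.00136, and 0.492 with an estimated correlation). Cell cycle genes were lower for 5 of 8 and higher for 0, with Mcm6 (−2.60), Mki67 (−1.51) and Rrm2 (−1.23) (adjusted p = 0.0375, and 0.606 with an estimated correlation).

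On HFD, fatty acid and triglyceride synthesis genes were lower in 129 for 15 of 18 and higher for 0, with Scd1 (−3.38), Acacb (−2.43), Fasn (−1.97) and Elovl6 (−1.88) (camera adjusted p = 4.28e-12, and 0.319 with an estimated correlation). Cholesterol genes were lower for 17 of 22 and higher for 0, with Mvd (−1.95) and Hmgcs1 (−1.89) (adjusted p = 7.34e-11, and 0.319 with an estimated correlation). Lipid droplet genes were lower for 9 of 14 and higher for 0 (9 and 1 adjusted over the list alone), with Fitm1 (−2.57), Cidec (−2.37) and Pparg (−2.14) (adjusted p = 0.000118, and 0.366 with an estimated correlation). Interferon genes were lower for 11 of 14 and higher for 1, with Oasl1 (−2.19) and Irf7 (−1.38) (adjusted p = 0.000118, and 0.319 with an estimated correlation). Cell cycle genes were lower for 6 of 8, with Mcm6 (−3.00) and Top2a (−1.68) (adjusted p = 0.00137, and 0.319 with an estimated correlation). Stellate cell markers were lower for 8 of 10, with Col1a1 (−2.61) and Col3a1 (−2.21 ± 0.21) (adjusted p = 6.65e-05, and 0.147 with an estimated correlation). Kupffer cell markers were lower for 10 of 13 (11 adjusted over the list alone), with C1qa (−1.36) and C1qc (−0.97) (adjusted p = 0.000129, and 0.42 with an estimated correlation). Of 3 adipocyte markers Cfd was lower (adjusted p = 0.0353, and 0.366 with an estimated correlation).

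On chow 5976 genes differed between the strains (limma, adjusted p below 0.05), 2872 higher in 129 and 3104 lower, and on HFD 3647, 2146 higher and 1501 lower. At least 2-fold differences were seen for 982 genes on chow (537 higher, 445 lower) and 630 on HFD (270 higher, 360 lower). Of the calls, 807 were higher in 129 on both diets (546 for independent lists), 935 lower on both (413 for independent lists) and 359 opposite (972 for independent lists). The GC and length correction turned 116 of the calls on chow and 0 of those on HFD. With the Mir6236 covariate 1445 genes differed on chow and 3355 on HFD, and the cell cycle list on chow (median −1.08 before and −0.677 with it, adjusted p = 0.0581) and the adipocyte list on HFD (−0.573 and −0.176, adjusted p = 0.09) did not pass.

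Clock genes oscillated in every set. Of 19 core clock and output genes, the 24 h cosine test (limma F test, adjusted p below 0.05) called 14 in B6 chow, 13 in B6 HFD, 18 in 129 chow and 17 in 129 HFD, with median amplitudes of 1.09, 1.01, 1.46 and 1.20 log2. Arntl, the gene of the activator BMAL, peaked at ZT 23.39 ± 0.55 in B6 chow, 21.62 ± 0.58 in B6 HFD, 23.49 ± 0.55 in 129 chow and 22.31 ± 0.55 in 129 HFD. Its output gene Dbp peaked nearly opposite, at ZT 11.29, 9.71, 11.62 and 10.44. Among clock genes rhythmic on both diets, peaks on HFD were earlier by a median of −1.4 h in B6 (11 of 12 genes) and of −1.18 h in 129 (16 of 17 genes). Gene by gene, the limma test of a rhythm change with diet called 0 of 19 clock genes in B6 (0 adjusted over the list alone) and 1 in 129, Per2 (change vector 0.93, adjusted p = 0.0437, 0.103 after the GC and length correction and 0.745 with the Mir6236 covariate), with Per2 and Rora adjusted over the list alone. Strain shifted clock peaks by a median of −0.02 h on chow and 0.19 h on HFD. Per2 (adjusted p = 0.0117), Nr1d1 (0.0174) and Nr1d2 (0.0466) differed in rhythm between the strains on chow (3 adjusted over the list alone), and none of the 3 did after the GC and length correction (adjusted p = 0.143, 0.0698 and 0.108) or with the Mir6236 covariate (0.292, 0.266 and 0.508). On HFD 0 clock genes differed.

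**Figure D3:**
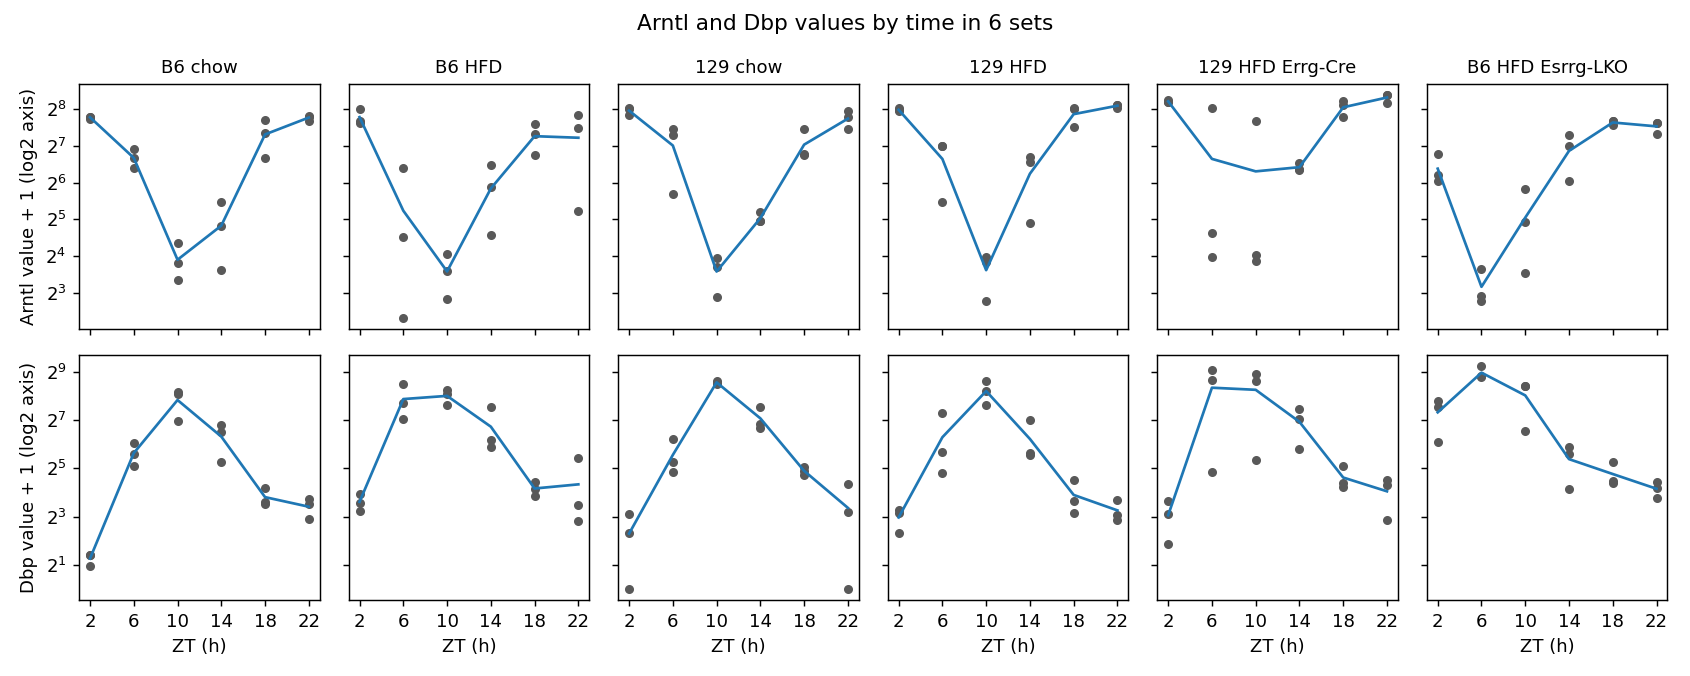
Deposited values plus 1 of the clock gene Arntl and its output gene Dbp (vertical axes, log2 scale) against zeitgeber time (horizontal axis, h) in the 6 sets. Each point is a library and the line joins the means of 3 replicates. Arntl peaked between ZT 21.62 and 23.49 in the wild-type sets and at ZT 19.22 in the libraries labelled Esrrg LKO, which were normalised separately.

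Over all genes, clock genes included, the strongest rhythms in B6 chow were those of Dbp (amplitude 2.73 ± 0.33), the metallothionein gene Mt2 (2.65), Nr1d1 (2.61), Npas2 (2.45), the phosphate transporter gene Slc34a2 (2.43), Rgs16 (2.32), Ciart, Bhlhe41, Myom3 and Arntl. In B6 HFD, Rgs16 (2.45), the cell cycle inhibitor gene Cdkn1a (2.26), Moxd1 (2.19) and the retinoic acid hydroxylase gene Cyp26b1 (2.18) stood beside Dbp (2.46). In 129 chow the largest amplitudes were those of Mir6240 (4.64), Mir6236 (4.55), Rgs16 (3.71) and the feeding-induced gene Angptl8 (3.58, peak at ZT 18.74), followed by Dbp (3.26), Ciart (2.98), Npas2 (2.81), Tsku (2.79), Mt2 (2.71) and G0s2 (2.67). Mir6240 did not pass with the Mir6236 covariate (adjusted p = 0.123). In 129 HFD the largest amplitudes were those of Npas2 (2.82), Dbp (2.54), Ciart (2.48), Cdkn1a (2.46), Tubb2a (2.43) and Cyp2b10 (2.40). The rhythms of Angptl8, Rgs16 and G0s2, an inhibitor of triglyceride lipolysis, changed with HFD in 129 (vectors 2.75, 3.02 and 2.38, adjusted p = 0.0442, 0.0491 and 0.0339), where their amplitudes were 0.90, 1.12 and 0.41. The same genes differed between the strains on chow (vectors 3.37, 2.51 and 2.47, adjusted p = 0.00196, 0.043 and 0.00459), with Zfhx2 (2.78), Mbd6, Atn1 and Rpl36. None of the named changes with diet in 129 (10 genes) or differences on chow (11 genes) passed with the Mir6236 covariate.

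The number of rhythmic genes was 695 in B6 chow, 461 in B6 HFD, 5395 in 129 chow and 795 in 129 HFD (limma, adjusted p below 0.05). In 129 chow 37.2% of the rhythmic genes peaked at ZT 4 to 8 and 25.1% at ZT 16 to 20, and these shares were 18.28% and 31.4% after the GC and length correction. With the Mir6236 covariate 1662 genes were rhythmic in 129 chow, including 1485 of the 5394 called without it, whose median amplitude went from 0.53 to 0.31 (median standard error 0.12 and 0.13). The counts were then 938 in B6 chow, 533 in B6 HFD and 996 in 129 HFD. Of the rhythmic genes, 205 were shared between the diets in B6 (28.4 for independent lists), 659 between the diets in 129 (380), 472 between the strains on chow (332) and 233 on HFD (32.5). Fitted with their own set alone, 3969 genes were rhythmic in 129 chow and 2756 in 129 HFD, so the contrast between the 129 sets depends on the spread being shared. A rhythm change with diet was called for 6 genes in B6 (Phlpp2, Dclre1c, Sult1a1, Gpd2, Rad21 and Herc1), of which Dclre1c (vector 0.88) and Sult1a1 (0.82) passed after the GC and length correction, and for 142 genes in 129, led by Mir6240 (4.96) and Mir6236 (4.65), or 11 genes with the Mir6236 covariate. That count in 129 depends on single libraries, from 35 without 129 chow ZT6 replicate 1 or 129 HFD ZT2 replicate 2 to 491 without 129 chow ZT14 replicate 1, and was 11 at most without all libraries of 1 replicate number. Between the strains, rhythms differed for 1476 genes on chow (659 after that correction and 77 with the Mir6236 covariate) and for 5 on HFD, among them Tubb2a (1.98), Mug2 (1.23), Urml (1.20) and Ero1lb (0.83). The count on chow is reached by 5 of 100 random regroupings (highest other 3113), so chance is not excluded for it. It ran from 774 without 129 chow ZT6 replicate 1 to 2745 without 129 chow ZT14 replicate 1, and was 538, 8 and 930 without all libraries of replicate 1, 2 and 3. The diet by strain interaction of the rhythm was called for 0 genes (limma, 1046 at an unadjusted p below 0.05).

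In the libraries labelled Esrrg LKO, 18 of 19 clock genes were rhythmic, with a median amplitude of 1.15. Arntl peaked at ZT 19.22 ± 0.42, Dbp at ZT 6.79 ± 0.38, Per2 at ZT 10.39 and Cry1 at ZT 16.37, against ZT 21.62, 9.71, 13.89 and 19.92 in wild-type B6 HFD. All 13 clock genes rhythmic in both sets peaked earlier, by a median of −3.54 h (−4.42 to −2.4 h). The tables were normalised separately, and an effect of the genotype was not tested. In all, 727 of 11946 genes were rhythmic, led by Npas2 (2.81), Dbp (2.40), the deubiquitinase gene Usp2 (2.17), Arntl (2.15), Rgs16 (2.06) and Upp2 (2.05). In the Errg-Cre libraries 17 of 19 clock genes were rhythmic, with Arntl at ZT 21.56 ± 0.74 against 22.31 in wild-type 129 HFD, and 12 of 15 clock genes rhythmic in both sets peaked earlier (median −1.1 h). In 2 of these libraries Arntl and Dbp stood opposite to their group mates, while Nr1d1 and Per2 did so only in part. Arntl and Dbp were at 260 and 28.2 in ZT6 replicate 3 (mates 23.7 and 407, 14.5 and 531). In ZT10 replicate 3 they were at 206 and 39.3 (mates 13.6 and 395, 15.4 and 475). This library was close to ZT18 replicate 1 in Arntl, Dbp, Nr1d1 and Per2 (220, 32.8, 19.3 and 251 there). Nr1d1 in ZT6 replicate 3 (208, mates 323 and 193) and Per2 in ZT10 replicate 3 (246, mates 229 and 346) lay between their mates, whereas Per2 in the former (72.8, mates 205 and 287) and Nr1d1 in the latter (16.2, mates 129 and 111) lay below. Without these 2 libraries, an exclusion chosen after seeing the data, Arntl peaked at ZT 21.19 ± 0.33, the median shift was −0.83 h and 1599 genes were rhythmic. Mup14 (amplitude 4.07 ± 0.91 before and 3.54 ± 1.02 after, adjusted p = 0.0613) and Mup11 (3.44 ± 0.76 and 3.02 ± 0.85, adjusted p = 0.0564) then did not pass. There 2076 of 11622 genes were rhythmic (1402 after the GC and length correction and 908 with the Mir6236 covariate), led by Mup14 (4.07), Mup11 (3.44), Npas2 (2.50) and Dbp (2.40). The count was 1245 without ZT6 replicate 1 and 1265 without ZT10 replicate 2.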

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

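The tests of GC content and length, shallow libraries, the shared spread, the Mir6236 level and the order of clock genes, and the ranges of the ratios with 1 library left out, were chosen after the results were seen, while the other tests of the clock and the random regroupings were planned. The genes and lists of the next paragraph stand out because the diet effect differed between the strains by the test of the difference (129 minus B6, log2). The other patterns were noticed in the counts and the clock peaks.

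In all 3881 genes differed. Random regroupings of the libraries gave 2012 at most, and 1 of 100 (the real one) gave as many. They mix libraries of both diets or strains, so they do not test equal diet effects in the strains. Among the lists, the median differences were −0.638 for fatty acid and triglyceride synthesis, −0.491 for lipid droplet genes, −0.0475 for mitochondrial and ERR targets, 0.304 for heat shock genes, 1.3 for male-biased genes, −0.8 for stellate cell markers and −1.54 for the 3 adipocyte markers. None of the 7 lists passed with an estimated correlation (adjusted p = 0.196 to 0.798), and lipid droplet genes did not pass with the GC and length trend removed (0.069), though their median was then −0.446. These (median −0.116) and the mitochondrial list (0.0183) did not pass with the Mir6236 covariate. Genes that responded higher in 129 were Cyp2c40 at 5.2, Sult1e1 at 4.76, Cyp2c69 at 4, the protocadherin gene Pcdh11x at 3.9, Asns at 3.64, Tcf24 at 3.09, Ugt2b38 at 2.91, Obp2a at 2.69, Mup8 at 2.68 and Alb at 2.58. Genes that responded lower in 129 were Mir6236 at −6.45, Mir6240 at −6.19, Cfd at −4.92, Rpph1 at −3.88, Apoa4 at −2.98, Amdhd2 at −2.61, the complex I subunit gene Ndufb7 at −2.56, Hist1h4d at −2.49, the pentose phosphate gene Pgls at −2.4 and the linker histone gene Hist1h1c at −2.38. All 20 genes keep their call and sign with the GC and length trend removed. With the Mir6236 level as a covariate 6 of the 19 others keep them (Cyp2c40, Sult1e1, Cyp2c69, Tcf24, Obp2a and Cfd), and Ndufb7 changed sign. Reads of the Cyp2c, Ugt2b, Mup and histone genes can be shared between copies, and Alb is saturated.

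Diet changed 3.28 times as many genes in B6 as in 129. Leaving out the shallow libraries left a ratio of 2.65 (2.34 to 3.08 with 1 further library left out), above the limit of 1.5, so they do not account for the whole difference. Removing the GC and length trend of each library left 2.19 (1.87 to 2.36), which argues against this trend as the whole cause. In fits over only the groups compared the removal took the ratio from 2.33 to 1.43 (1.30 to 1.66), on both sides of the limit, so part of the difference goes with the trend. The 2.33 before the removal (1.91 to 2.58) argues against a spread shared by the strains as the whole cause. With array weights, which let the scatter differ between libraries, the ratio was 1.59, but 0.269 and 0.346 without B6 chow ZT14 replicate 2 or 1 and 2.68 without 129 chow ZT6 replicate 2, which decides nothing. With the Mir6236 level as a covariate the ratio was 0.216, with 564 genes in B6 and 2606 in 129, and 0.0585 without 129 chow ZT14 replicate 1. That level differs between B6 chow and B6 HFD, and the covariate raised the median standard error of the called effects 1.71 times in B6 and shrank the effects. What sets the Mir6236 level therefore cannot be told apart from diet in B6 for most genes. A stronger diet response of B6 liver is an untested hypothesis.

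In 129 chow 6.79 times as many genes were rhythmic as in 129 HFD. Against B6 chow the ratio was 7.76 (11.96 without B6 chow ZT14 replicate 3). Without the shallow libraries the ratio to 129 HFD was 5.61 (4.51 to 6.90 with 1 further library left out), so they do not explain it. With the GC and length trend removed it was 3.84 (3.18 to 4.66) against 129 HFD and 4.02 (3.21, to 6.50 without B6 chow ZT14 replicate 3) against B6 chow, so the trend is not the whole cause. Fitted with each set alone the ratio to 129 HFD was 1.44, from 0.957 without 129 chow ZT6 replicate 1 to 1.80 without 129 chow ZT6 replicate 3, and with array weights 1.93 (1.43 to 2.15), so a spread shared by sets of unequal scatter stays open there. The trend removal gave 1.08 in that fit, which decides nothing on the trend because the ratio was within 1.5 before it. Against B6 chow the ratio was 9.92 with each set fitted alone (6.60 without 129 chow ZT6 replicate 1), and 7.15 with the trend removed as well (3.62 without B6 chow ZT14 replicate 3), which argues against a shared spread as the whole cause there. Array weights gave 2.06, from 1.52 without 129 chow ZT6 replicate 2 to 3.20 and 3.60 without B6 chow ZT6 replicate 3 or ZT10 replicate 1 and 4.98, 4.66 and 5.30 without B6 chow ZT22 replicate 1, 2 or 3. All lie above 1.5, but most of the excess was gone, as with time as a factor (1.97) or 2 within-group axes removed (2.40). With the Mir6236 covariate the ratio was 1.67 against 129 HFD (1.36 to 2.02) and 1.77 against B6 chow (1.38, to 2.95 without B6 chow ZT14 replicate 3). These ranges hold the limit, so the level stays open as the cause, and most of the excess went with it. In 129 chow the Mir6236 level parts the libraries along time, apart from ZT14 replicate 1, so a daily rhythm and a difference in the libraries are confounded for those genes. A richer rhythm of 129 on chow stays a hypothesis.

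Clock genes peaked earlier in the libraries labelled Esrrg LKO than in wild-type B6 HFD. Differences between pairs of clock genes peaked earlier by a median of −3.4 h, in all 76 pairs rhythmic in both sets. That test assumed that normalisation shifts a whole library, which quantile normalisation does not, so the order of 2 clock genes within a library was tested as well. A normalisation that keeps ranks cannot change this order, and it peaked earlier by a median of −3.27 h, in 54 of 55 pairs that switched order in both sets, which argues against the separate normalisation of the tables. Leaving out 1 library at a time left a median shift of −3.26 h at the nearest to 0, so no single library accounts for it. A difference between the experiments other than the genotype cannot be told apart from the genotype, because 0 control libraries of that experiment were used here. An effect of the knockout on clock phase is thus untested.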

How the results depend on the processing

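Removal of the GC and length trend or of within-group axes, the Mir6236 covariate, the exclusion of shallow libraries, of 1 library and of 2 libraries standing apart in clock state were chosen after seeing the data. Counts of genes are called similar here when within 1.5 times the reported count. Under this measure the diet effect in B6 was similar in 17 of 19 settings (564 to 7994), the diet effect in 129 in 15 of 19 (556 to 5030), the interaction in 10 of 17 (14 to 6071), the strain effects on chow and HFD in 15 and 16 of 19, and the list tests in 6 of 7. Rhythmic counts were similar in 11 of 19 settings in B6 chow and B6 HFD, 15 of 19 in 129 chow, 12 of 19 in 129 HFD, 9 of 17 in Errg-Cre and 11 of 16 in Esrrg LKO. Rhythm changes were similar in 9 of 19 settings for diet in B6, 7 of 19 for diet in 129, 8 of 19 between strains on chow, 10 of 19 on HFD and 15 of 17 for the interaction. Except where the setting itself tests fewer genes or samples, the cause was not tested. The unknown depth limits all counts.

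With a pseudocount of 0.1, rhythms differed between the strains on HFD for 3 genes. With no filter the rhythm change with diet in 129 counted 31 genes, the rhythm difference between strains on chow 839 and rhythmic genes in Errg-Cre 1201. With the filter at 100, which tests fewer genes, the counts were 3976 for diet in B6, 2585 for the interaction, 3418 and 2264 for strain on chow and HFD, and 3336 rhythmic genes in 129 chow.

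Array weights gave 5030 genes for diet in 129, 6071 for the interaction and 6156 for strain on HFD. They gave 3395 rhythmic genes in B6 chow, 858 in B6 HFD, 3609 in 129 HFD and 3261 in Errg-Cre. Rhythm changes then numbered 745 for diet in B6, 4252 for diet in 129, 4220 between strains on chow, 31 on HFD and 640 for the interaction. With time as a factor 2916 genes varied in B6 chow, 785 in B6 HFD, 1319 in Errg-Cre and 433 in Esrrg LKO, with 407 changed by diet in B6 and 1 for the interaction. Fits over only the groups compared gave 400 rhythmic genes in B6 chow, 154 in B6 HFD and 2756 in 129 HFD, and rhythm changes of 0 for diet in B6, 222 for diet in 129 and 434 between strains on chow.

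Removing the GC and length trend left 1927 genes for the interaction and 659 for the rhythm difference between strains on chow, and turned the diet effects in B6 of Atf4 (−0.055) and Hspb1 (−0.18), neither past the threshold. With the same removal in fits over only the groups compared, counts were 3229 for diet in 129, 3737 for strain on chow, and 457, 248, 3266 and 3012 rhythmic genes in B6 chow, B6 HFD, 129 chow and 129 HFD. Rhythm changes were then 0 for diet in B6, 437 for diet in 129 and 280 between strains on chow, with Atf4 at −0.055 and Hspb1 at −0.18 again. Removing 2 within-group axes gave 3133 genes for diet in 129, 1758 for the interaction and 3942 for strain on chow. It gave 1691 rhythmic genes in B6 chow, 1120 in B6 HFD, 1688 in 129 HFD and 1793 in Esrrg LKO, with rhythm changes of 75 for diet in B6, 225 for diet in 129 and 22 between strains on HFD. In that setting the diet effects in B6 turned for Sds (−0.32), Hspa5 (0.048), Hspb1 (−0.22), Ccne2 (0.093), Hba-a2 (−0.40) and Hba-a1 (−0.52). The interaction turned for Prodh (0.052), Hba-a2 (0.19) and Hba-a1 (0.28), and the strain effect on chow for Pcx (−0.022), Trf (−0.050), Hba-a2 (−0.095) and Hba-a1 (−0.19).

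With the Mir6236 level as a covariate 564 genes changed with diet in B6, 14 differed by the interaction and 1445 between strains on chow. There were 1662 rhythmic genes in 129 chow and 908 in Errg-Cre, and rhythm changes of 11 for diet in 129 and 77 between strains on chow. The diet effects in B6 turned for Per1 (−0.031), Nr1d1 (−0.28), Sds (−0.16), Hspb1 (−0.22), Stab2 (−0.013), Hba-a2 (−0.61) and Hba-a1 (−0.56). The interaction turned for Ndufb7 (0.050), Nr1d1 (0.28), G0s2 (0.12), Pnpla2 (0.38), Pcx (0.17), Cox4i1 (0.067), Uqcrc1 (0.075), Prodh (0.34), Apob (−0.43), Ttr (0.13), C1qa (0.046), Ccr2 (−0.39), Stab1 (0.32), Hba-a2 (0.85), Hba-a1 (0.74) and Lipe (0.028), and the strain effect for Nr1d1 on chow (−0.051) and Esrra on HFD (0.058), none past the threshold.

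Without the shallow libraries rhythm changes numbered 14 for diet in B6, 281 for diet in 129 and 9 between strains on HFD. With an estimated correlation 1 list test passed.

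Leaving out replicate 1, 2 or 3 of every group, which leaves fewer samples, gave 162 to 398 rhythmic genes in B6 chow, 140 to 223 in B6 HFD, 235 to 508 in 129 HFD, 368 to 495 in Errg-Cre and 166 to 481 in Esrrg LKO, and at the lowest 2160 in 129 chow. Rhythm changes ranged from 0 to 0 for diet in B6 (limma), 0 to 11 for diet in 129, 8 to 930 between strains on chow and 0 to 1 on HFD. The interaction ranged from 1296 to 3455, and diet in 129 and strain on HFD reached 556 and 2077 at the lowest.

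Leaving out a single library moved only rhythm counts by more than 1.5 times. The most it gave was 2391 genes for diet in 129, 4408 for the interaction, 3859 for strain on HFD, and 836, 537, 5993, 753, 2558 and 860 rhythmic genes in B6 chow, B6 HFD, 129 chow, 129 HFD, Errg-Cre and Esrrg LKO. The difference between strains on chow was 774 and 2695 without 129 chow ZT6 replicate 1 or 3, 956 without ZT2 replicate 3, 2745 without ZT14 replicate 1, and 841 and 2321 without B6 chow ZT18 replicate 2 or ZT6 replicate 3. The change with diet in B6 was 10 without B6 chow ZT10 replicate 3 or B6 HFD ZT2 replicate 1, ZT6 replicate 1, ZT10 replicate 2 or ZT18 replicate 1. On HFD the strain difference was 15 without B6 HFD ZT2 replicate 2, 9 without ZT14 replicate 1 and 2 to 3 without ZT6 replicate 3, ZT10 replicates 1 or 2 or ZT22 replicate 3, and 8 without 129 HFD ZT22 replicate 1 and 2 to 3 without ZT6 replicate 1 or ZT10 replicates 1 or 3. The change with diet in 129 was, by 129 chow replicate left out, 44 and 45 (ZT2, 2 and 3), 35, 47 and 469 (ZT6, 1 to 3), 491 and 91 (ZT14, 1 and 3), 75, 43 and 43 (ZT18, 1 to 3) and 66 (ZT22, 2). By 129 HFD replicate left out it was 81, 35 and 94 (ZT2, 1 to 3), 76, 69 and 38 (ZT6, 1 to 3), 90 and 94 (ZT10, 1 and 3), 46 and 38 (ZT14, 2 and 3), 58, 80 and 40 (ZT18, 1 to 3) and 71 (ZT22, 2). Errg-Cre counted 1245 rhythmic genes without ZT6 replicate 1 and 1265 without ZT10 replicate 2.

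The replicate numbers do not pair the samples: deviations of libraries with the same number had a mean correlation of 0.0035, against −0.0019 for different numbers, and 31 of 72 libraries correlated best with their own number. With the replicate number as a block the counts were 6770 for diet in B6, 2062 for diet in 129, 3877 for the interaction, 5963 and 3639 for strain on chow and HFD, 683, 445, 5362 and 785 rhythmic genes in the 4 wild-type sets, 1789 in Errg-Cre and 720 in Esrrg LKO, and 36 list tests passed.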

Other observations

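All values in this part that concern B6 HFD ZT22 replicate 3, the exclusion of that library or of shallow libraries, the removal of the GC and length trend and the Mir6236 covariate were chosen after the result was seen, while the regroupings were planned.

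A single liver library held a granulocyte and cell division profile. In B6 HFD ZT22 replicate 3 the neutrophil alarmin genes S100a8 and S100a9 stood at 6588 and 7952, against 271 and 383 in the next highest of the other 107 libraries, which include separately normalised tables. The granule genes Mpo (1162 against 44.7), Ngp (2585 against 161), Camp (595 against 47.7) and Elane (171 against 11.8) were highest there too, as were the proliferation genes Mki67 (1132 against 217) and Top2a (630 against 79.6). Of 17 acute phase genes 9 were at their highest there, with Hpx at 376870 against 48228 and Orm2 at 19287 against 3435. Erythroid genes were low, with Hbb-bs at 30.5 and Alas2 at 181, both the lowest of all libraries. The library's values correlated with those of its group mates at 0.875. Without it the diet effect in B6 counted 6787 genes, the interaction 4030 and the strain effect on HFD 3672, and 39 list tests passed in place of 35. No explanation was tested.

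Strain differences of the other lists on chow did not pass the camera test, though some passed in alternatives. Kupffer cell markers were lower in 129 for 8 of 13 and higher for 0, with Marco at −2.04 and Vsig4 at −1.06 (adjusted p = 0.0526). This list passed with the replicate number as a block (0.0411), without the shallow libraries (0.0403), without B6 HFD ZT22 replicate 3 (0.0349), with the GC and length trend removed (0.000497) and with the Mir6236 covariate (0.000566), but not with an estimated correlation (0.798). Gluconeogenesis genes were higher for 8 and lower for 1 of 16, with the serine dehydratase gene Sds at 1.34 and Pcx at 1.09 (adjusted p = 0.0747). Amino acid genes were higher for 8 and lower for 2 of 15 (8 and 3 adjusted over the list alone), with Got1 at 1.14 and Ass1 at 0.93 (adjusted p = 0.0868, and 0.0125 with the trend removed, with 10 higher and 1 lower). Fatty acid synthesis genes were higher for 3 and lower for 7 of 18 (3 and 9 adjusted over the list alone), with Me1 at −1.43 and Srebf1 at 1.13 (adjusted p = 0.24, 0.00146 with the trend removed and 0.00186 with the Mir6236 covariate). Bile acid genes were higher for 6 and lower for 2 of 17, with Nr0b2 at 1.97 and the sterol exporter gene Abcg8 at 1.44 (adjusted p = 0.246, and 0.0149 with the trend removed). Mitochondrial and ERR targets were higher for 8 and lower for 3 of 21, with Esrra at 1.57 (adjusted p = 0.15, and 0.00704 with the trend removed). Male-biased genes on chow (adjusted p = 0.0868) passed with the trend removed (0.0491) and with the covariate (0.0197), and lipid droplet genes (0.523) with the covariate (0.0174). On HFD, acute phase genes were higher in 129 for 5 of 17 and lower for 0, with Orm3 at 1.99 and Apcs at 1.57 (adjusted p = 0.363), and the list passed without B6 HFD ZT22 replicate 3 (adjusted p = 0.0329). Male-biased genes on HFD were higher for 7 and lower for 3 of 13, with Cyp4a12a at 3.04 and Serpina1e at −3.94 (adjusted p = 0.606).

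Random regroupings of the libraries (100 each, the real one included) argue against chance for the diet and strain effects, each with a share of 1 in 100, the smallest possible. Only the real grouping reached the counts for diet in B6 (6792, highest other 3136) and 129 (2071, highest other 1). The same held for strain on chow (5976, highest other 4361) and on HFD (3647, highest other 1). Rhythmic genes in B6 chow were as many in 2 regroupings (695, highest other 1002). No other regrouping gave as many for B6 HFD (461, highest other 106), 129 chow (5395, highest other 3724), 129 HFD (795, highest other 1), Errg-Cre (2076, highest other 5) and Esrrg LKO (727, highest other 0). The rhythm change with diet in 129 was reached by 1 (142, highest other 6). Chance cannot be excluded for the rhythm change with diet in B6 (6 genes, reached by 6 regroupings, highest other 4576) and the rhythm differences between the strains on chow (1476 genes, reached by 5, highest other 3113) and on HFD (5 genes, reached by 5, highest other 394). For the rhythm interaction the regroupings decide nothing, because a count of 0 (limma, 1046 at an unadjusted p below 0.05) is reached by all 100 (highest other 2615). Regroupings that called several times the real count, as for the rhythm change with diet in B6 and the strain difference on HFD, point to a structure of the samples. These regroupings mix libraries of both diets or strains, so the group effects themselves are not ruled out as its origin, and this was not tested here.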
